A study of Mus musculus with 12 samples.

How the data were processed

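The data are spatial transcriptomes of mouse tissue sections made with Well-ST-seq, in which messenger RNA from a cryosection is captured on an array of small wells whose barcode records the well. The 12 libraries comprise 1 adult brain section at 10 µm, 1 adult brain section at 20 µm, 3 embryo sections at 10 µm, 6 embryo sections at 30 µm and 1 section labelled adult spleen at 10 µm. Per the labels, all animals were C57BL/6J females, embryos were at embryonic day 13.5 and adults were 12 weeks old. Per the labels' protocols, tissue was permeabilised for 12 minutes and libraries were amplified with a high-fidelity PCR kit. The labels give total RNA as the molecule for both brain libraries and polyA RNA for the others.

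The authors deposited, for each library, a matrix of whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalised. The submitters' processing notes name Space Ranger 1.1.0 and the mm10 mouse genome. The annotation is not given in the sources used here. Well positions were not used here, so a spot is known only by its barcode and no map was drawn. The deposited counts had been through different barcode selection. All 6 libraries at 10 µm and 20 µm held a full grid of 58 by 58 or 60 by 60 barcode parts, whereas each 30 µm library held part of a grid. The smallest count per barcode was 391, 400, 403 and 402 UMIs in Embryo 4, Embryo 5, Embryo 7 and Embryo 9, and 37 and 187 UMIs in Embryo 6 and Embryo 8. Libraries at 10 µm and 30 µm shared 0 barcodes, so barcode set, barcode selection and resolution cannot be told apart.

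The 2 brain matrices had 33696 rows while the gene table deposited with them had 31253 lines. Taken row by row, log2 CPM (UMIs of a gene per 1000000 UMIs of a library) in the brain correlated across genes with those of the other libraries at r of 0.0178 at most. Rows of the brain matrices were therefore given no gene names. Brain marker lists, the brain CPM without mitochondrial genes and Malat1, and the brain part of the tissue comparison were not run.

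A spot was kept with at least 50 UMIs, and whether it lay under tissue was not assessed here. UMIs were summed over the kept spots of each section, because the section is the replicate and spots are not. Replicates were compared before averaging, with a chi-square test of the summed counts of every pair of embryo sections. The smallest chi-square per degree of freedom over the 36 pairs was 2.80, between Embryo 6 and Embryo 7, so no pair agreed within sampling noise and each section counted as 1 replicate. This comparison does not show that sections are independent: other pairs of 30 µm sections gave 15.6 or more, so Embryo 6 and Embryo 7 stood far closer than the rest. Leaving out either of them counts the pair once, and both fits are among the alternatives. The labels number the embryos and do not say which plane a section shows or whether sections share a litter, so p-values measure the spread between these sections.

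Summed counts of the 3 and 6 embryo sections were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, low counts removed with filterByExpr, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3. CPM of named genes compared between embryo sections used totals scaled by the TMM factors, from 0.775 in Embryo 7 to 1.30 in Embryo 4. CPM elsewhere were not scaled, as for list sums, regions, Xist, the brain and the library labelled spleen. Marker lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, and again with an estimated correlation. The 14 embryo lists covered neurons, neural progenitors, fetal liver, erythroid cells, skeletal muscle, cardiac muscle, cartilage, osteoblasts, mesenchyme, epithelium, endothelium, macrophages, proliferation and immediate early stress genes. UMIs per spot, genes per spot, shares of transcript classes and co-detection were compared with two-sided exact permutation tests over the 84 splits of 9 sections into 3 and 6, which give a smallest p of 0.0238. Benjamini-Hochberg adjustment was made over each family of these tests, and under an alternative beside the other tests of the family as run under it, where they were. Co-detection was the number of spots with a UMI of both lists over the number expected from independence, after every spot was thinned to 200 UMIs. A section expected to have fewer than 5 such spots got no value. Thinning left out 1942 spots of Embryo 1, 494 of Embryo 2 and 3 of Embryo 3. At 30 µm it kept 2626 of 2681 spots of Embryo 6, and Embryo 8 also lost spots.

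Spots with at least 200 UMIs were clustered in each library with the Leiden method (leidenalg 0.10.2, resolution 0.8, 15 neighbours, 20 principal components of 2000 variable genes), with the genes of the lists chosen before the data were examined left out of the clustering and those of the kidney lists kept in it. Clusters are called regions by their leading genes, the 5 with the highest CPM over the rest of the library among genes found in at least 25% of the region's spots. Intervals for single libraries are 95% exact Poisson for counts, and they cover counting error only.

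Lists, tests, the rule for named genes and most alternatives were chosen before the data were examined. The rule took, among genes past the threshold with a mean of at least 20 CPM and group ranges that did not overlap, the 10 with the largest change each way, and the 2 most abundant members of every embryo list. For the library labelled spleen it took the 10 genes with the highest ratio over the 10 µm embryo sections at 100 CPM or more, with a floor of 3 counts, and the 2 most abundant members of each spleen list. This part of the rule as first chosen compared with all other 10 µm libraries and named no floor. The brain was left out because its rows had no gene names. Predicted genes were passed over, and some genes that the rules took are not reported here. The 6 kidney lists and a minimum of 400 UMIs per spot were chosen after seeing the data. Alternatives were other spot minimums, other depths and seeds of thinning, other scalings, no count filter, voomWithQualityWeights, DESeq2 1.42.0, other clustering resolutions and leaving out each section. Simulated counts for the embryo comparison covered 13563 genes with 200 changed. From them edgeR recovered 19% of genes changed 2-fold and 69% of genes changed 4-fold, with 0 false calls. Simulated sections and genes varied independently, so the 0 false calls do not cover tissue differences shared by many genes. Clustering placed 100% of the spots of 3 simulated regions. Gene positions come from the GRCm38.p6 annotation by symbol, which held 25966 of the 31253 listed genes.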

Results

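Well-ST-seq was applied to mouse tissue at several well sizes, and the design asks how the readout changes with resolution and tissue. The 9 embryo sections, 3 at 10 µm and 6 at 30 µm, form the replicated comparison. Total depth was 726769, 2572527 and 4500039 UMIs in Embryo 1, Embryo 2 and Embryo 3 at 10 µm. At 30 µm it was 2561144, 7218278, 7276046, 6872091, 3848679 and 4397993 UMIs in Embryo 4 to Embryo 9. The brain libraries held 13129798 UMIs at 10 µm and 21532252 UMIs at 20 µm, and the library labelled spleen held 8625563 UMIs. The brain libraries and the library labelled spleen had no replicates.

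Of the genes fixed as markers, 10 of 10 neuron genes had a lower and 10 of 10 mesenchyme genes a higher estimate in the embryo sections at 10 µm than at 30 µm. Past an edgeR adjusted p of 0.05 were 8 of the neuron genes and 2 of the mesenchyme genes. With an estimated correlation, both lists had a camera adjusted p = 0.477. Nova1, a neuronal splicing regulator on chromosome 12 from 46697895 to 46819480, had 5.51 ± 1.16 CPM (SD, n = 3) at 10 µm and 103 ± 61.0 CPM (SD, n = 6) at 30 µm. Postn, which encodes the matrix protein periostin and lies on chromosome 3 from 54359267 to 54391041, had 542 ± 347 CPM (SD, n = 3) at 10 µm and 114 ± 72.3 CPM (SD, n = 6) at 30 µm. Of 13563 genes tested with edgeR's quasi-likelihood test, 1407 passed an adjusted p of 0.05, of which 578 were higher and 829 lower at 10 µm. With library size scaling alone, 850 genes passed and 24% of them were higher at 10 µm, against 41.1% with TMM, 55.1% of 2118 genes with voomWithQualityWeights and 50% of 1142 genes without Embryo 3. Resolution cannot be told apart from barcode set and barcode selection here. The labels do not give the plane of a section, so the tissue that each section holds cannot be told apart from resolution either. The call depended on single sections: edgeR called 0 genes without Embryo 1 and 0 without Embryo 2 (3621 and 3236 genes at an unadjusted p under 0.05), 2961 without Embryo 4, 454 without Embryo 6, 509 without Embryo 7, 318 without Embryo 8 and 424 without Embryo 9.

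Among the 10 genes taken for the largest fall at 10 µm, the host gene Mir124a-1hg was lower by 4.37 on the log2 scale (SE 0.656, edgeR adjusted p = 0.0188), with 3.38 ± 3.12 CPM against 47.7 ± 20.0 CPM. Ptpn5, which encodes a brain tyrosine phosphatase, had 1.89 ± 1.66 CPM against 47.3 ± 28.0 CPM, and the transporter gene Slc6a15 had 1.68 ± 1.78 CPM against 40.2 ± 23.9 CPM. Pou3f2, a transcription factor of neural development, had 4.51 ± 3.72 CPM against 52.9 ± 24.6 CPM. Mir124-2hg, Irx2, Ube2ql1, Igfbpl1 and Sez6l completed the 10 and were between 9.93-fold and 12.5-fold higher at 30 µm. Of the sections at 30 µm, Embryo 4 was the lowest for all 10 genes. Ptpn5 had 3.61 CPM there, against at most 3.08 CPM at 10 µm and 61.8 to 67.4 CPM in Embryo 6 to Embryo 9. Igfbpl1 had 52.1 CPM in Embryo 4, against at most 28.1 CPM at 10 µm. The group means therefore do not describe every section at 30 µm. Among the 10 genes taken for the largest rise, Mfap4, a microfibril gene, had 225 ± 64.1 CPM at 10 µm and 54.2 ± 19.5 CPM at 30 µm (edgeR adjusted p = 0.0188). Mgp, an inhibitor of matrix calcification, had 185 ± 54.8 CPM against 56.4 ± 20.5 CPM, and Igfbp3, a binding protein of insulin-like growth factors, had 224 ± 67.4 CPM against 54.6 ± 30.9 CPM. Pkdcc, Cd3eap, Olfml3, Shisa2, Itga5 and Pnpla7 were between 3.25-fold and 4.05-fold higher at 10 µm. Of the 23 named genes past the threshold, 23 did not pass edgeR's test without Embryo 1 and 23 without Embryo 2.

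Among the lists, 10 of 10 measured neuron genes had a lower estimate at 10 µm. Adjusted over all genes 8 of them passed, and 10 of 10 passed when adjusted over the list alone. Tubb3, a neuronal tubulin, had 106 ± 57.9 CPM against 585 ± 265 CPM (edgeR adjusted p = 0.0297), while Stmn2 had 155 ± 82.9 CPM against 628 ± 386 CPM (edgeR adjusted p = 0.0686). The median log2 change of the neuron list was -2.56, with a camera adjusted p = 5.13e-08 at the preset correlation and an adjusted p = 0.477 with an estimated correlation. All 8 neural progenitor genes had a lower estimate at 10 µm. Adjusted over all genes 2 passed, among them Sox2 at 24.0 ± 18.9 CPM against 84.8 ± 24.2 CPM. Adjusted over the list alone, 5 passed. The progenitor list had a median of -1.62, a camera adjusted p = 3.61e-04 and an adjusted p = 0.477 with an estimated correlation. Without Embryo 3 its median was -3.36, 7 members passed when adjusted over the list alone and the adjusted p was 0.0613 with an estimated correlation. All 10 mesenchyme genes had a higher estimate at 10 µm. Adjusted over all genes 2 passed, Postn and Col3a1, the latter at 1757 ± 675 CPM against 888 ± 152 CPM. Adjusted over the list alone, 7 passed. That count was 1 without Embryo 1, 0 without Embryo 2, 3 without Embryo 6, Embryo 7 or Embryo 8, 4 without Embryo 9, 2 with library size scaling and 4 with a minimum of 200 or 400 UMIs or with sections thinned to the smallest total, while the neuron count was 10 in each of these fits. The mesenchyme list had a median of 0.94, a camera adjusted p = 3.39e-04 and an adjusted p = 0.477 with an estimated correlation. The epithelium list had a median of 1.34 and a camera adjusted p = 0.0130, with 0 of 9 members past the threshold and an adjusted p = 0.80 with an estimated correlation. Without Embryo 3 the epithelium median was 0.06 and its camera adjusted p was 0.297. Adjusted over all genes, 0 members of these 4 lists passed without Embryo 1 or Embryo 2, and 2 neuron genes and 0 of the others passed without Embryo 6, Embryo 7, Embryo 8 or Embryo 9.

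The other 10 embryo lists did not pass camera. The adjusted p was 0.0755 for macrophage genes, of which 1 of 9 passed singly as higher at 10 µm and 8 had a higher estimate. It was 0.108 for cartilage, endothelium and proliferation genes, of which 0 passed singly. It was 0.121 for erythroid, 0.512 for skeletal muscle, 0.669 for osteoblast, 0.688 for fetal liver, 0.714 for cardiac muscle and 0.997 for immediate early stress genes. With a section left out, some of these lists passed camera: erythroid, skeletal muscle and cartilage without Embryo 1 (adjusted p = 0.0136, 0.0346 and 3.42e-04), proliferation without Embryo 2 or Embryo 5 (0.0164 and 0.0403), endothelium and macrophage without Embryo 3 (0.0300 and 0.00106), cartilage and macrophage without Embryo 6 (0.0412 and 0.0233), and macrophage without Embryo 7 (0.0385). With an estimated correlation, the adjusted p of these lists in these fits was between 0.344 and 0.818. Hbb-y, an embryonic globin gene, had 4216 ± 1058 CPM at 10 µm and 6088 ± 1876 CPM at 30 µm (edgeR adjusted p = 0.318). Col2a1, the main cartilage collagen gene, had 860 ± 405 CPM and 697 ± 180 CPM (edgeR adjusted p = 0.553). Sections of equal resolution also differed in content. The neuron list summed to 837 CPM in Embryo 4 and 1497 CPM in Embryo 5, and lay between 3164 and 3584 CPM in the other 4 sections at 30 µm. The skeletal muscle list summed to 1495 CPM in Embryo 2 and to 6.95 and 58.0 CPM in Embryo 1 and Embryo 3.

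**Figure D1:**
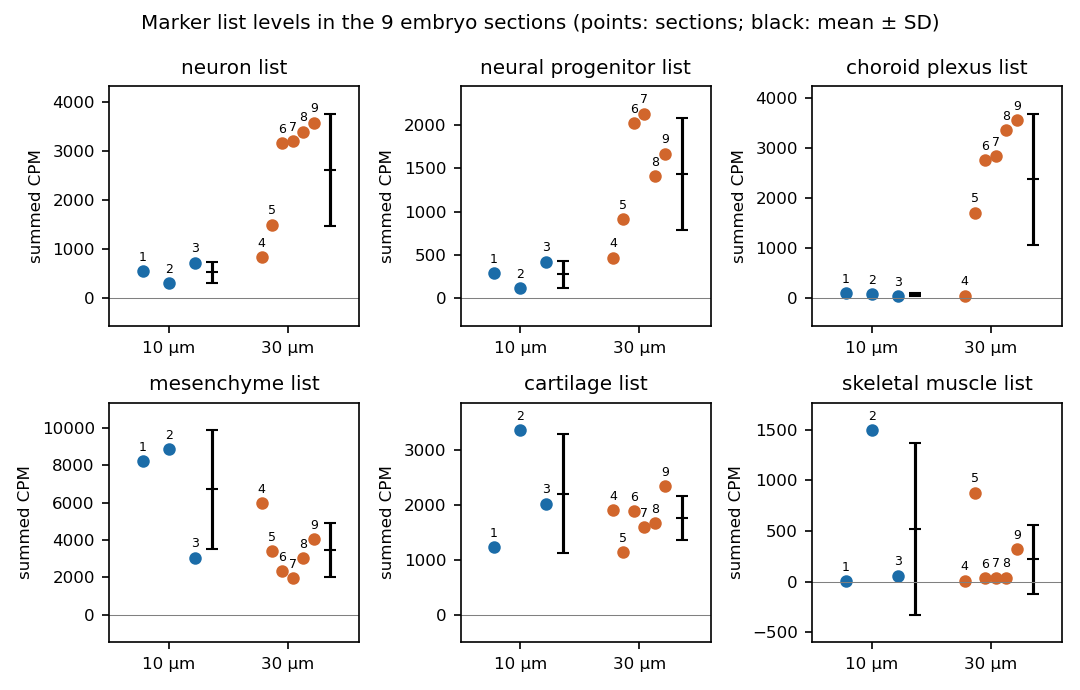
Summed CPM of 6 marker lists (vertical axes) in the 3 sections at 10 µm and 6 sections at 30 µm, with points numbered by embryo and black bars for mean ± SD. The neuron list lies between 302 and 724 CPM at 10 µm and between 837 and 3584 CPM at 30 µm.

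Spots at 30 µm held more UMIs in total and more detected genes than spots at 10 µm. The median was 2117 ± 543 UMIs per spot (SD, n = 6) at 30 µm and 660 ± 504 UMIs (SD, n = 3) at 10 µm, and the mean log2 values differed 4.05-fold by an exact permutation test (p = 0.0238, adjusted p = 0.0357), while the square of the resolution differs 9-fold. These spots had been through unlike barcode selection. The smallest deposited count was 6, 7 and 79 UMIs in Embryo 1, Embryo 2 and Embryo 3. It was 391, 400, 403 and 402 UMIs in Embryo 4, Embryo 5, Embryo 7 and Embryo 9, and 37 and 187 UMIs in Embryo 6 and Embryo 8. The 4.05-fold difference therefore does not measure well size alone. Genes per spot differed 4.09-fold by an exact permutation test (p = 0.0238, adjusted p = 0.0357), from 352 ± 265 genes at 10 µm to 1098 ± 89.7 genes at 30 µm. After thinning to 200 UMIs, the values were 143 ± 28.7 genes at 10 µm and 170 ± 8.81 genes at 30 µm, which did not pass (exact permutation p = 0.0714). No transcript class share passed. Mitochondrial transcripts, led by mt-Co3 and mt-Atp6, made up 4.01% ± 0.817 and 4.49% ± 0.870 of UMIs (exact permutation, adjusted p = 0.452). Haemoglobin transcripts made up 1.29% ± 0.333 and 1.73% ± 0.321 (exact permutation, adjusted p = 0.238). Ribosomal protein transcripts made up 30.9% ± 2.71 and 26.0% ± 6.85 (exact permutation, adjusted p = 0.413). The nuclear RNA Malat1 made up 0.0181% ± 0.00749 and 0.00732% ± 0.00244 (exact permutation p = 0.0476, adjusted p = 0.190). With any 1 section left out, neither UMIs nor genes per spot passed adjustment, as the smallest exact permutation p was then 0.0714 without a 10 µm section and 0.0357 without a 30 µm section. Without Embryo 1 the differences were 2.42-fold for UMIs and 2.36-fold for genes, and without Embryo 3 they were 6.18-fold and 6.21-fold. They were also smaller with a minimum of 400 UMIs per spot, chosen after seeing the data. Median UMIs in Embryo 1, Embryo 2 and Embryo 3 were then 509, 706 and 1194.

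**Figure D2:**
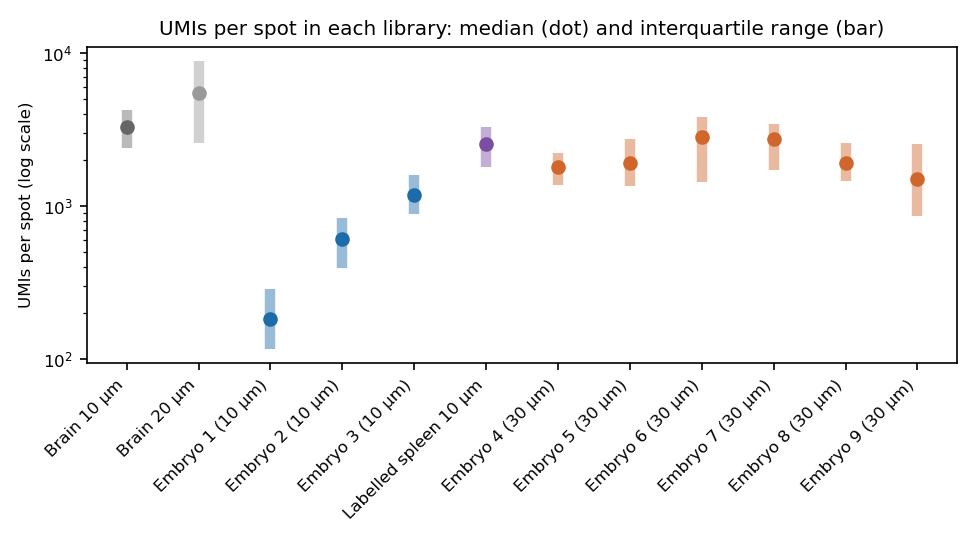
UMIs per spot on a log scale in each of the 12 libraries, with the median as a dot and the interquartile range as a bar. Embryo 1, Embryo 2 and Embryo 3 at 10 µm have medians of 183, 608.5 and 1188 UMIs, and the sections at 30 µm have medians from 1504 to 2818 UMIs.

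After thinning to 200 UMIs, no pair of lists passed adjustment, while 4 pairs passed with another seed of thinning and 4 after thinning to 100 UMIs. The values of cartilage genes sharing a spot did not overlap between the 10 µm and 30 µm sections. Thinning equalised UMIs alone, as the thinned spots of Embryo 1 still had a median of 110 genes, against 160 to 181 genes in the sections at 30 µm. Spots with cartilage genes from both parts of the cartilage list were 1.08, 1.42 and 1.89 times the number under independence in Embryo 1, Embryo 2 and Embryo 3 and between 2.08 and 3.77 times in the sections at 30 µm (exact permutation p = 0.0238, adjusted p = 0.0556). Neuron and mesenchyme genes met 0.938 to 1.01 times as often as under independence at 10 µm and 0.620 to 0.860 times at 30 µm (exact permutation p = 0.0238, adjusted p = 0.0556). Neuron and erythroid genes met 1.04 to 1.16 times as often as under independence at 10 µm and 0.932 to 1.02 times at 30 µm (exact permutation p = 0.0238, adjusted p = 0.0556). Within the mesenchyme list the values were 1.03 to 1.15 and 1.14 to 2.29 (exact permutation p = 0.0476, adjusted p = 0.0833). The highest possible value falls as more spots hold a UMI of the list. The mesenchyme list summed to 6712 ± 3177 CPM (SD, n = 3) at 10 µm and 3453 ± 1445 CPM (SD, n = 6) at 30 µm. The erythroid list summed to 12933 ± 3340 CPM (SD, n = 3) at 10 µm and 17295 ± 3208 CPM (SD, n = 6) at 30 µm. Values of pairs with either list therefore do not share the same upper limit in the groups. Of 13 pairs, 7 had enough spots in both groups for a test. With another seed, the adjusted exact permutation p was 0.0476 for neuron with erythroid genes, for neuron with mesenchyme genes, within cartilage and within mesenchyme. After thinning to 100 UMIs it was 0.0357 for neuron with erythroid genes, for neuron with mesenchyme genes, within cartilage and within the erythroid list. After thinning to 500 UMIs no pair passed, with a smallest adjusted exact permutation p of 0.119.

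**Figure D3:**
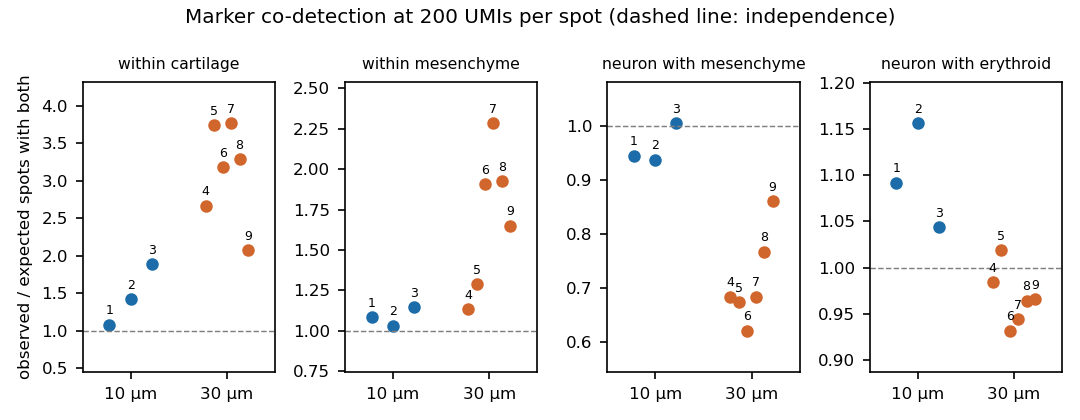
Observed over expected number of spots with both marker sets (vertical axes) at 200 UMIs per spot, with points numbered by embryo. The within-cartilage value is at most 1.89 at 10 µm and at least 2.08 at 30 µm.

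Regions of the 30 µm embryo sections differed in their leading genes, and the regions described here were picked after those genes were seen. A region led by Matn1 and Acan, which encode cartilage matrix proteins, covered 47 spots of Embryo 5, where the cartilage list stood 38.8-fold over the rest of the section. A region led by the potassium channel genes Kcnj13 and Kcne2 covered 46 spots of Embryo 7, and the choroid plexus list stood 54.3-fold over the rest. A region of 133 spots in Embryo 5 was led by the muscle genes Mybph, Mylpf and Ttn, with the skeletal muscle list at 24.2-fold. Other regions of Embryo 5 were led by Gad2 and Sst, by Neurod2 and Tbr1, and by the eye genes Atoh7, Trpm1 and Pmel. Regions led by Hox genes and Lamp5 appeared in Embryo 6, Embryo 7, Embryo 8 and Embryo 9. Camk1d, Cdk8, Lars2, Gphn and Cmss1 led a region of 330 spots in Embryo 6, with a median of 536 UMIs against 2862 UMIs over all clustered spots of that section, and some of them were among the leading genes of regions in Embryo 5, Embryo 7 and Embryo 9. At 10 µm, Embryo 3 had a region of 232 spots led by Hapln1 and Mia, with the cartilage list at 5.21-fold, while regions of Embryo 1 were led mostly by ribosomal protein genes. Matn1, Acan and Hapln1 are members of the cartilage list and Mylpf of the skeletal muscle list, so the folds of these lists are no separate evidence beside the leading genes. Over all 12 libraries there were 101 regions, with 57 after thinning to 200 UMIs or at a resolution of 0.4 and 149 at a resolution of 1.2.

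The brain comparison gives depth and similarity, since its rows carry no gene names. Spots of the 20 µm brain section had a median of 5481 UMIs and 2601 genes, and those of the 10 µm section 3266 UMIs and 1818 genes. The ratios were 1.68 for UMIs and 1.43 for genes, while the square of the resolution differs 4-fold. Log2 CPM correlated across rows at r = 0.993, where rows are not independent replicates. Of 1969 rows with at least 100 CPM in either section, 5 were more than 2-fold higher and 6 more than 2-fold lower at 20 µm. Matrix row 30020 had 665 CPM at 10 µm and 3777 CPM at 20 µm, a log2 ratio of 2.51 with a 95% exact interval from counting error of 2.48 to 2.54. Matrix row 30 had 158 CPM at 10 µm and 47.4 CPM at 20 µm. With 1 section each there is no replicate check.

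The library labelled spleen carried kidney transcripts at high level and few lymphoid transcripts. Klk1, a tissue kallikrein gene on chromosome 7 from 44225360 to 44229622, had 17036 CPM (95% Poisson interval 16949 to 17123) and was at least 4088-fold higher than in any 10 µm embryo section, where it had 0 UMIs. Umod, which encodes the uromodulin of the loop of Henle, had 4822 CPM (4775 to 4868) and was at least 1157-fold higher. Pck1 and Miox, enzymes of the proximal tubule, had 4945 and 3041 CPM, and S100g, Gpx3, Fxyd2, Spink1 and Egf had 8054, 28099, 6983, 2215 and 2036 CPM. The spleen lists summed to 397 CPM over 8 lists, against 482 CPM in the highest embryo section. Ighm, the heavy chain gene of B cells, had 5.68 CPM (4.20 to 7.51), Cd79b had 1.39 CPM and the T cell genes Lck and Cd3g had 2.78 and 2.32 CPM. The marginal zone macrophage genes Marco and Cd209b had 0 UMIs, with an upper limit of 0.428 CPM. Some lists of other tissues were high here too: the osteoblast list summed to 2878 CPM, the choroid plexus list to 1245 CPM and the cerebellar list to 1274 CPM, of which Calb1, also a distal tubule gene, made up 1267 CPM. The plasma cell genes Xbp1 and Igha had 106 and 82.4 CPM. Because these levels go against the label, no result of this library is given as spleen.

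The kidney lists, chosen after these genes had been seen, summed to 42988 CPM over 6 lists, against 103 CPM in the highest embryo section. Proximal tubule genes summed to 24645 CPM, distal tubule genes to 10433 CPM, loop of Henle genes to 5875 CPM, collecting duct genes to 1139 CPM, intercalated cell genes to 576 CPM and podocyte genes to 321 CPM. Of its 7 regions, the region led by Nphs1 and Wt1, genes of the glomerular filter, covered 172 spots. A region of 403 spots was led by Slc26a4 and Atp6v1g3 of intercalated cells, and a region of 483 spots by Pvalb and Slc12a3 of the distal convoluted tubule. The genes of the kidney lists took part in this clustering, so the regions are no separate evidence for the lists.

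**Figure D4:**
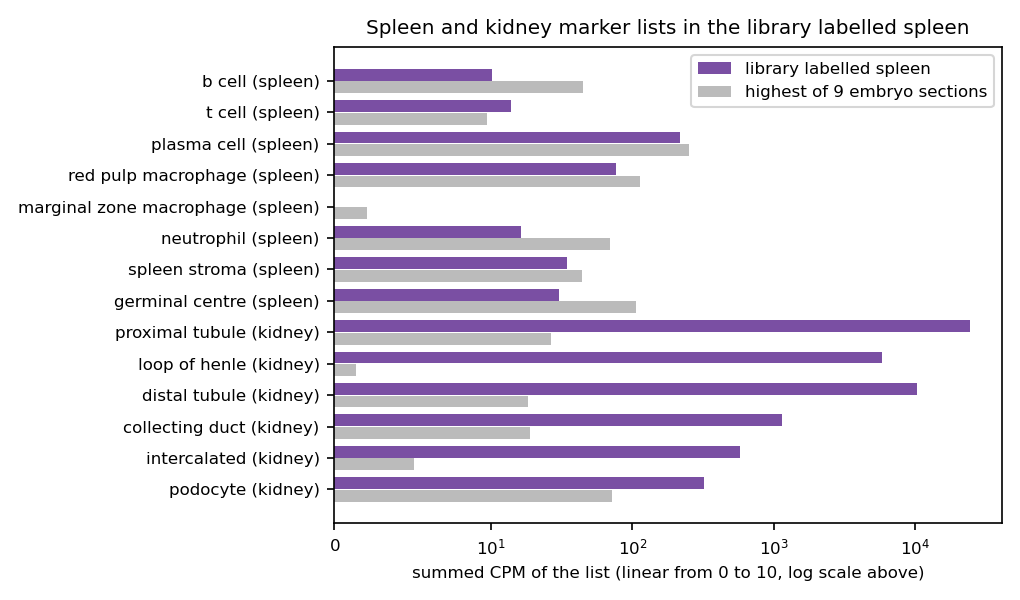
Summed CPM of 8 spleen lists and 6 kidney lists in the library labelled spleen and in the highest of 9 embryo sections, on an axis that is linear from 0 to 10 CPM and logarithmic above. The proximal tubule list reaches 24645 CPM, and the B cell list 10.2 CPM.

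Xist, the transcript of the inactive X chromosome (chromosome X, 103460373 to 103483233), was detected in all 10 libraries with gene names, from 33.0 to 198 CPM. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y together had between 2 and 16 UMIs per library, so Xist exceeded them at least 17.8-fold in each. All 10 libraries were labelled female.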

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

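Muscle transcripts stood apart in Embryo 5 among the 6 sections at 30 µm. The skeletal muscle list summed to 878 CPM there against 10.5 to 321 CPM in the others, Mylpf had 185 CPM against 0.903 to 36.9 CPM, and Actc1 had 164 CPM against 0.301 to 48.3 CPM. Embryo 4 had the highest Runx2, a bone regulator, at 59.0 CPM against 11.3 to 19.7 CPM, the highest Epcam at 44.6 CPM against 4.33 to 17.5 CPM, and the highest Col3a1 at 1176 CPM against 741 to 901 CPM. Xist in Embryo 4 was 198 CPM against 51.8 to 101 CPM. In this paragraph the list sum and Xist are unscaled CPM, and the other genes are given in TMM-scaled CPM. Each of these 7 values, of 79 quantities examined, lay farther from the nearest section, relative to the range of the 6, than Dixon's 95% critical value. Chance flags about 1 in 20 groups of normally distributed values, so some of the 79 quantities would be flagged by chance. Mylpf and Actc1 belong to the skeletal muscle list, so the 7 flags are not separate.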

How the results depend on the processing

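In this part, the minimum of 400 UMIs was chosen after seeing the data. UMIs and genes per spot kept their direction and side of the threshold under all spot filters and with means in place of medians. Leaving out a section kept the direction, with log2 differences from -2.63 to -1.28 for UMIs and from -2.64 to -1.24 for genes, but ended the call, as fewer splits give a smallest p of 0.0714 or, adjusted, 0.0536. The genes called numbered 669 at 400 UMIs, 850 with library size scaling only, 785 thinned to the smallest section, 2118 with voomWithQualityWeights and 2460 with DESeq2, and 0 to 2961 without a section. Beyond fewer sections or genes, the cause was not tested. Lists past camera numbered 0 with an estimated correlation and 4 to 7 without a section. Epithelium did not pass when thinned to the smallest section (adjusted p = 0.0613). Erythroid genes passed with voomWithQualityWeights (0.0266), macrophage genes with library size scaling (0.0235) and no count filter (0.0306), and cartilage genes at 400 UMIs (0.0497), and with an estimated correlation these 4 fits gave 0.559 to 0.702. Co-detection pairs past the threshold numbered 4 at 100 UMIs and 4 with another seed, against 0 at 200 and at 500 UMIs. Thinning to 200 UMIs or a resolution of 0.4 gave 57 regions, and a resolution of 1.2 gave 149, against 101. A minimum of 10% of the 99th percentile of UMIs gave brain ratios of 1.90 for UMIs and 1.53 for genes. Without mitochondrial and haemoglobin genes, kidney lists summed to 45973 CPM and spleen lists to 425 CPM in the library labelled spleen. Of 23 named genes called, 23 lost the call without Embryo 1 and 23 without Embryo 2. Over all named genes, other processing left 491 gene results as they were, ended 13 calls, added 9 and turned 10 signs. Sign changes came in results not past the threshold. With single sections left out, the log2 change ran from -2.45 to 2.58 for the skeletal muscle list, -2.74 to 2.10 for cardiac muscle, -0.021 to 0.62 for cartilage, -0.20 to 0.76 for osteoblasts and -0.080 to 0.098 for immediate early stress genes, which gave 0.059 with no count filter and 0.044 with voomWithQualityWeights. It ran from -2.21 to 2.31 for Tnnt2, -2.16 to 2.56 for Actc1, -0.021 to 0.62 for Col11a1, -0.10 to 0.59 for Col2a1, -2.33 to 3.24 for Mylpf, -3.26 to 1.90 for Myh7 and -0.47 to 2.13 for Epcam. Jun ran from -0.45 to 0.21, Tyrobp from -0.29 to 0.20, Dnajb1 from -0.055 to 0.098 and Cdh5 from -0.21 to 0.25. With other processing, Jun gave 0.079 at 400 UMIs and 0.054 with voomWithQualityWeights, Myh7 -0.17 and Trf -0.0019 with voomWithQualityWeights, and Tyrobp 0.083, Cdh5 -0.021 and Dnajb1 -0.058 with library size scaling. Dnajb1 gave -0.00031 with all barcodes, -0.031 with no count filter and -0.0058 with DESeq2. The brain CPM without mitochondrial genes and Malat1, brain lists and the brain part of the tissue comparison were not run. No paired analysis was possible because the groups share no replicate numbers. Depth limits Embryo 1 most, with 183 UMIs per spot.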

Other observations

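Choroid plexus and inhibitory neuron genes separated the embryo sections without having been listed for the embryo. The choroid plexus list, led by Ttr, summed to 97.2, 80.5 and 44.4 CPM in Embryo 1, Embryo 2 and Embryo 3 and to 53.9 CPM in Embryo 4, against 1707 to 3560 CPM in Embryo 5 to Embryo 9. The inhibitory neuron list summed to 27.0 ± 13.0 CPM (SD, n = 3) at 10 µm and 222 ± 120 CPM (SD, n = 6) at 30 µm, with Embryo 4 at 14.4 CPM. Excitatory neuron genes were highest in Embryo 4, at 263 CPM, where Neurod2 and Neurod6 led a region. Neither list was tested between resolutions.

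Cmss1, Cdk8, Camk1d, Gphn and Lars2, chosen after they were seen to lead shallow regions, together had 4481, 2000 and 7831 CPM in Embryo 4, Embryo 8 and Embryo 9, and 466 to 947 CPM in Embryo 5, Embryo 6 and Embryo 7. They had 1234, 819 and 529 CPM in Embryo 1, Embryo 2 and Embryo 3. In the 25% of spots with the fewest UMIs their CPM was 25.4 times that in the 25% with the most in Embryo 6, between 1.48 and 7.65 times in Embryo 5, Embryo 7, Embryo 8 and Embryo 9, between 1.07 and 1.51 times in the 10 µm embryo sections and 0.835 times in Embryo 4. Ribosomal protein transcripts made up 19.3%, 24.6% and 16.8% of UMIs in Embryo 4, Embryo 8 and Embryo 9, 30.1% to 32.6% in Embryo 5, Embryo 6 and Embryo 7 and 29.0% to 34.0% in the 10 µm embryo sections. UMIs per spot also followed the barcode: the part of the barcode that explained most of the variance of log2 UMIs explained 21.9% in the 10 µm brain and 55.9% in the 20 µm brain, against at most 2.70% in 100 shuffles of the latter. In the embryo sections that part explained from 27.1% in Embryo 6 to 50.5% in Embryo 2, against at most 4.82% in shuffles.

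In the paragraphs below, the tests of other splits, of thinned depth and of the library labelled spleen were chosen after their results had been seen, and the kidney lists after the data were seen. The tests of variation between regions for genes lower at 10 µm, of shallow 30 µm spots and of kidney co-detection were fixed before their results were seen, and the values for genes higher at 10 µm had no prediction.

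The 1407 genes that separated 10 µm from 30 µm embryo sections exceeded every other split, since 1 of the 84 splits, the real one, gave as many and the highest other gave 625, from Embryo 1, Embryo 2 and Embryo 4. After every section was thinned to the smallest total, 47.3% of the genes were still called. Lower total depth at 10 µm therefore does not account for all of the calls. This thinning equalised section totals and not UMIs per spot, so lower depth per spot stays open. In 6 of 6 sections at 30 µm, genes lower at 10 µm varied between regions more than 95% of 1000 matched random sets. So did genes higher at 10 µm. The random sets were matched on counts only, and called genes outside the lists could take part in the clustering. The test therefore cannot decide whether different tissue in the sections accounts for the calls. List sums do show that content differed, also among sections of equal resolution. The choroid plexus list summed to 44.4 to 97.2 CPM at 10 µm and to 53.9 CPM in Embryo 4. It summed to 1707 to 3560 CPM in Embryo 5 to Embryo 9. How many of the calls follow from such content was not tested. The plane of each section is not given and the barcode sets differ fully with resolution. An effect of section content, of the array or of the barcode selection on these genes therefore stays open.

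The co-detection value within cartilage genes was lower in all 3 sections at 10 µm than in the sections at 30 µm, but the difference did not pass at 200 or 500 UMIs (exact permutation adjusted p = 0.0556 and 0.119) and passed at 100 UMIs (0.0357) and with another seed (0.0476). At 200 UMIs the exact permutation p was 0.0238, the smallest that the splits allow. Whether it passed adjustment there therefore depended on the other pairs and not on the size of the cartilage difference. If the difference holds, it may follow from lower original depth or from RNA moving between wells, and no biological explanation was tested. Shallow spots of the 30 µm sections, with at most 1188 UMIs, stayed above the highest 10 µm cartilage value in 0 of 6 sections, but 4 of these sections had too few spots for a value and the other 2 gave 1.40 and 1.57, so lower original depth stays open. The median within kidney lists in the library labelled spleen was 1.1, below the cartilage value of 1.89, as mixing of RNA in all 10 µm wells would give. That test was void, because 3 of the 4 kidney lists were so abundant that their value could not exceed 1.89, while collecting duct genes, which could, reached 1.73.

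The kidney transcripts in the library labelled spleen are consistent with a kidney section under a wrong tissue label, with kidney lists 108-fold over spleen lists. Kidney RNA carried into a spleen section is argued against by the B cell and T cell lists, which together were at 0.445 of the highest embryo section, although the T cell list alone was above it, at 13.9 against 9.72 CPM, and Igha had 82.4 CPM against 0 in the embryo sections. Gene names out of step with the matrix rows are argued against by the correlation across genes of log2 CPM with embryo sections, which was at least 0.791. Whether the label or the deposited matrix is at fault stays open.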
